A study of Mus musculus with 2 samples.

How the data were processed

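RNA was measured in 2 libraries of 1 group, each made from a pool of 50 layer 5 pyramidal neurons of male mice aged 8 months. Per the labels' protocols, cells were taken by laser capture and libraries were made by a Smart-seq type protocol, which copies full-length RNA without molecular identifiers. The labels name the strain B6NCrl in one field and C57Bl5 and C57Bl6 in others, and an antibody tag reads Control. Replicate numbers come from the labels, and no further grouping exists, so no batch could be examined.

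For each library the authors deposited a gene table with an expected count, which is an estimated number of reads per gene and not normalized. The same deposited tables hold TPM, scaled to a fixed sum over all features of the file including spike-ins, and FPKM, scaled by effective length and depth. The posterior standard deviation of each count, per the file headers, was used only as a measure of how uniquely reads were assigned. A transcript table was used for replicate 1, in which the deposited percent gives each transcript's share of its gene's TPM. Quantification was derived from transcriptome alignments on mm10 with the GENCODE M4 annotation, per the text files deposited with the tables. The aligner, the quantifier and the use of strand are not given in the sources used here. If reads were counted without strand, overlapping genes such as Malat1 and Gm37376 share reads, and near-identical copies such as the hemoglobin genes and mitochondrial pseudogenes share reads in any case.

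Symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, the same build, by gene identifier without its version, and 42462 of 43346 gene identifiers matched. The other 884 held 0.194% and 0.179% of gene counts. Besides genes, each table lists 96 spike-ins and 26248 entries with numeric identifiers, which were left out of library sizes and comparisons.

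Depth was 24171434 estimated reads in replicate 1 and 27946180 in replicate 2. Expected counts were rounded to whole numbers for count methods. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), and the common dispersion was estimated with an intercept-only design over genes with rounded counts summing to at least 10. Ratios between libraries were log2((CPM + 1)/(CPM + 1)) over genes at mean CPM of at least 10. An exact conditional binomial test per gene, two-sided, compared the 2 counts given the library sizes, with Benjamini-Hochberg adjustment over 17796 genes. Floors of 3 reads per library and 95% exact intervals cover counting error only. Other values were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

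Before the data were examined, 35 gene lists were fixed: 12 of cell identity, 7 of cortical layers, 14 of function and 2 of sex. For each, the median TPM per library was placed among 10000 random lists of the same size drawn from 21474 protein-coding genes. Differences between lists are differences of medians of log2(TPM + 1) within a library, given as mean and SD over the libraries. The lists hold different genes and no reference tissue or other cell type was measured. Such a difference therefore does not measure enrichment or the share of a cell type or layer. List ratios were placed among 10000 random lists matched on mean expression in 20 bins. These percentiles describe the libraries and are not tests. Which lists were treated at length was decided after the values were seen, and every list is reported.

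The genes to be named were also fixed: the 3 members of each list with the highest mean TPM, 25 anchor genes of layers, cell types and sex, the 10 most abundant nuclear coding genes, and the 10 highest and 10 lowest ratios between the libraries. For transcripts they were the anchors at TPM of at least 10 and the 5 coding genes at TPM of at least 100 with the lowest leading share. Some genes that the rule selects are not reported here. Genes outside this rule are said to be chosen after their values were seen. Layer 5 and its subtype lists share members. So do the synaptic vesicle list and the pan-neuronal and glutamatergic lists.

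The dispersion and the 2-fold limit were tested on counts simulated with the means and sizes of these libraries, comparing replicate 1 with replicate 2. Simulated coefficients of 0.2, 0.4 and 0.6 were recovered as 0.229, 0.408 and 0.602 over 17515, 17428 and 17262 genes. Of 200 genes changed 4-fold, 98.5%, 86.0% and 74.5% lay beyond 2-fold, against 1.35%, 22.5% and 42.3% of unchanged genes. Each simulation gave all genes the same coefficient, whereas in the libraries it fell from 1.15 in the lowest abundance group to 0.211 in the highest. These rates therefore do not carry over to the real genes, of which 4.47% lay beyond 2-fold at mean CPM of at least 10. The list percentiles were tested on independent normal values, with the SD of the real ratios, given to 9189 genes. Of 100 unshifted lists of 10 genes 5 fell outside the central 95% of random lists, and all 100 lists shifted by 1 on the log2 scale did. Members of real lists can vary together, which this simulation does not cover. It also does not cover shorter lists, such as the 5 layer 6 or 3 erythroid genes compared below, or ratios that are not normally distributed.

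Alternatives were FPKM, TPM rescaled to nuclear coding genes, another pseudocount, means over members, filters on low values, DESeq2 1.42.0 size factors, total counts, spike-in totals, thinning to equal depth and leaving out each replicate. Figures were drawn with matplotlib 3.10.9.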

Results

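Gene expression was measured in layer 5 pyramidal neurons of adult mice, the excitatory projection neurons of a deep layer of the cerebral cortex. Each library was made from a pool of 50 laser-captured cells of wild-type males aged 8 months, from RNA longer than 200 nt, with synthetic spike-in RNAs added. There were 2 libraries, labelled biological replicates 1 and 2, in 1 group with no second condition. Both carry the same donor identifier, so the labels do not settle whether they came from different animals, and the spread between them may be technical. Comparisons were therefore made between gene groups within each library and between the libraries. With 2 libraries an exact two-sided test cannot give a p below 0.5, so no test between groups was run and values are given with their SD.

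Replicate 1 held 24171434 estimated reads and replicate 2 held 27946180, spike-ins included. At TPM of at least 1, 14057 genes were detected in replicate 1 and 13690 in replicate 2 (13874 ± 260, SD, n = 2), among them 11974 and 11691 protein-coding genes. Spike-ins took 4.28% and 5.32% of the estimated reads. Mitochondrial genes took 5.60% ± 0.42 (SD, n = 2) of the gene counts and ribosomal protein genes 1.23% ± 0.13. The 10 most abundant genes took 9.16% ± 0.31.

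The most abundant nuclear protein-coding transcripts included those of genes of calcium signalling, vesicle release and energy metabolism. Calm2, a calmodulin gene, stood at 6668 ± 736 TPM (SD, n = 2). Snap25, a SNARE protein of vesicle fusion, stood at 6077 ± 976. Pcp4, a calmodulin-binding peptide known from deep cortical neurons, stood at 3301 ± 1651. Cox8a, a subunit of cytochrome oxidase, stood at 3519 ± 85.8, and Usmg5, a subunit of ATP synthase, at 3466 ± 227. Other genes among the 10 highest included Ppia at 6702 ± 382, Tmsb4x at 4642 ± 1104, Fth1 at 3893 ± 152 and Ubb at 3338 ± 4.70 TPM.

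Pan-neuronal genes had the highest median of the cell identity lists in each library. The 15 pan-neuronal genes had a median of 175 TPM in replicate 1 and 261 TPM in replicate 2, above all 10000 random lists of coding genes in each library. All 15 were detected in each library, with Stmn3 at 1686 ± 372 TPM (SD, n = 2), Uchl1 at 790 ± 44.3, Thy1 at 156 ± 26.0 and the neurofilament Nefh at 33.2 ± 2.65. The 10 glutamatergic genes had medians of 58.3 and 66.8 TPM. Among them Nrgn, a postsynaptic calmodulin-binding protein, stood at 428 ± 132 TPM, Neurod6 at 96.1 ± 9.31, the kinase Camk2a at 83.9 ± 0.66 and the vesicular glutamate transporter Slc17a7 at 40.6 ± 12.3.

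GABAergic interneuron transcripts were nevertheless present in each pool. The 17 genes of that list had medians of 7.33 and 5.29 TPM, and 12 of them reached TPM of at least 1 in each library. The neuropeptide gene Sst (chromosome 16, 23889573 to 23890958) stood at 2506 TPM in replicate 1 and 844 TPM in replicate 2. Pvalb, a calcium-binding protein of fast-spiking cells, stood at 508 and 338 TPM, and the neuropeptide Npy at 529 and 202 TPM. The genes of the GABA-synthesising enzymes, Gad1 and Gad2, stood at 143 and 94.8 TPM and at 31.7 and 11.1 TPM. In replicate 1, for which transcript values were used, a transcript annotated as noncoding held 85.0% of the Gad1 TPM. The next transcript, annotated as protein-coding, held 8.43%, so most of this Gad1 value was not assigned to RNA that encodes the enzyme. For Gad2 a protein-coding transcript held 96.6%. The glutamatergic median exceeded the interneuron median by 3.06 ± 0.46 on the log2 scale (SD, n = 2). With the mean over members in place of the median this difference was 1.84 ± 0.85. The lists hold different genes and no reference tissue was measured, so these differences do not give the purity of the pools.

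Glial markers were detected in each pool and their medians lay below the glutamatergic median. Among random lists of coding genes the oligodendrocyte medians still lay at percentiles 99.3 and 98.5. The astrocyte medians lay at percentiles 97.0 and 98.7 and the microglial medians at 98.6 and 60.5. A high percentile among all coding genes therefore does not by itself mark neurons. The 16 astrocyte genes had medians of 11.9 and 15.1 TPM, 2.06 ± 0.06 below the glutamatergic median on the log2 scale, with the aldolase Aldoc at 299 ± 38.1 TPM, S100b at 139 ± 32.9 and the glutamine synthetase Glul at 99.6 ± 12.4. The astrocyte genes Aqp4 and Gfap were lower, at 4.91 ± 1.87 and 1.91 ± 0.42 TPM. For the 15 oligodendrocyte genes the medians were 18.3 and 14.6 TPM and the difference 1.80 ± 0.39, with the myelin gene Mbp at 247 ± 56.8 TPM and the iron carrier Trf at 96.4 ± 11.7. Microglial genes had medians of 15.97 and 2.64 TPM and a difference of 2.94 ± 1.74, which was 1.70 in replicate 1 and 4.17 in replicate 2. Among them were the complement gene C1qb at 26.6 ± 18.01 TPM and the adaptor Tyrobp at 26.2 ± 13.8, while the chemokine receptor Cx3cr1 stood at 2.03 ± 1.83. Oligodendrocyte precursor genes had medians of 4.26 and 1.13 TPM and a difference of 4.17 ± 1.10, with Vcan at 3.76 ± 2.76 TPM, Pdgfra at 3.59 ± 2.503 and Cacng4 at 3.11 ± 1.63.

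Vascular and connective tissue markers had lower medians than glutamatergic genes in each pool. Endothelial genes had medians of 2.68 and 2.71 TPM, 4.04 ± 0.17 below the glutamatergic median on the log2 scale (SD, n = 2), with Itm2a at 54.1 ± 16.6 TPM, Ly6c1 at 38.6 ± 5.64, Ly6a at 22.1 ± 1.28 and the tight-junction gene Cldn5 at 3.62 ± 1.90. Mural genes had medians of 0.17 and 0.29 TPM, with Vtn at 4.39 and 25.7, Acta2 at 11.6 and 0.21 and Rgs5 at 4.07 and 5.83 TPM. Fibroblast genes had medians of 0.23 and 0.035 TPM, with Igf2 at 1.74 ± 2.33, the proteoglycan Dcn at 1.51 ± 2.13 and the collagen Col1a2 at 0.36 TPM in each library. For ependymal and choroid plexus genes the medians were 0.02 and 0 TPM, with Folr1 highest at 0.33 ± 0.46. The differences from the glutamatergic median were 5.61 ± 0.07, 5.74 ± 0.35 and 5.90 ± 0.19 for the mural, fibroblast and ependymal lists. Their medians lie near 0 TPM, so the size of these differences depends on the pseudocount of 1. With a pseudocount of 0.1 they were 7.51, 8.22 and 9.08. With members at mean TPM of at least 1 the mural and fibroblast differences were 3.74 and 4.85. The erythroid list had a median of 1.23 TPM in replicate 1 and 69.6 TPM in replicate 2, so its difference of 2.26 ± 3.35 lay within the spread. The Y-linked genes Eif2s3y, Ddx3y and Uty stood at 71.6 ± 2.70, 22.5 ± 2.67 and 14.7 ± 2.496 TPM, the 4 Y-linked genes had medians of 19.4 and 18.6 TPM, and Xist and Tsix of the X-inactivation list had no reads in either library.

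**Figure D1:**
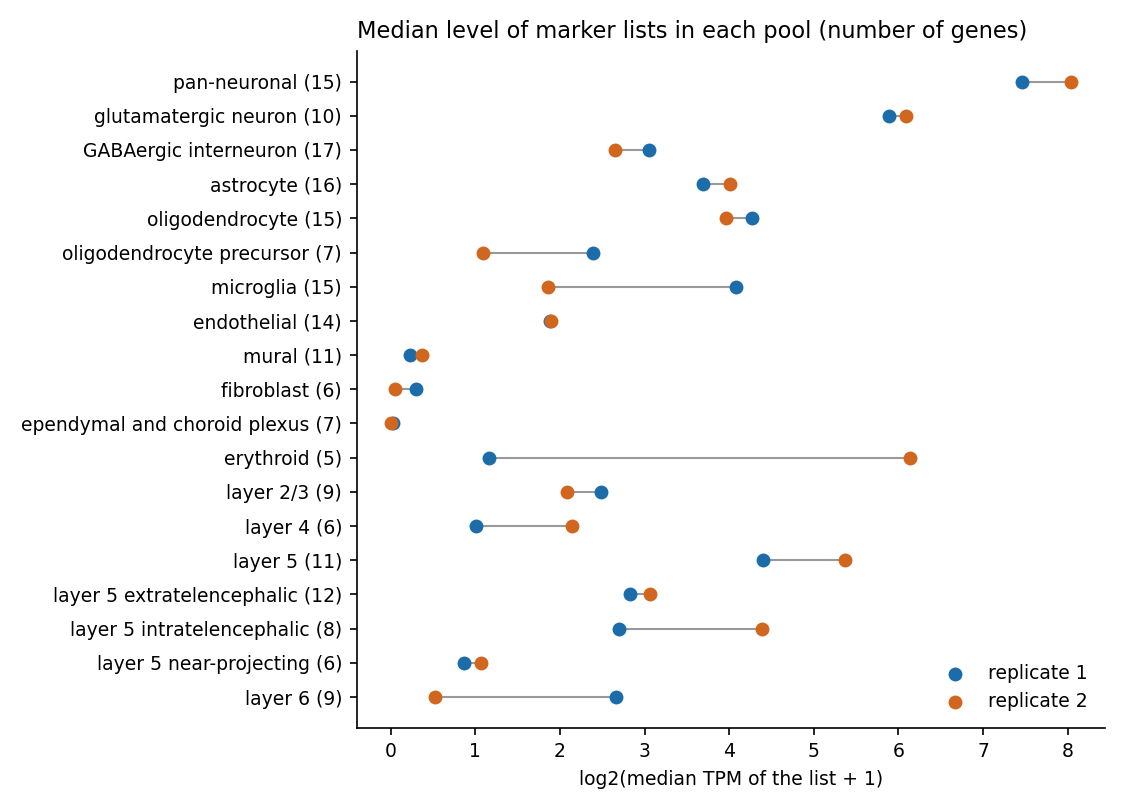
Median TPM of the 12 cell identity lists and 7 cortical layer lists in each pool, drawn as log2(median TPM + 1), with the number of genes in brackets; each point is 1 library and the grey line joins both. The pan-neuronal list lies highest, at 175 and 261 TPM, and the widest gap between the pools is that of the erythroid list, at 1.23 and 69.6 TPM.

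Among the cortical layer lists, the layer 5 list had the highest median in each library. The 11 layer 5 genes had medians of 20.0 TPM in replicate 1 and 40.4 TPM in replicate 2, and all 11 were detected in each. Besides Pcp4 (chromosome 16, 96467606 to 96525793), the retinol carrier Rbp4 stood at 84.1 ± 20.8 TPM (SD, n = 2), and Fezf2 and Bcl11b, transcription factors of subcortically projecting neurons, at 32.2 ± 17.2 and 11.2 ± 1.41. The gene of the transcription factor Etv1 stood at 54.5 ± 55.3. In replicate 1 a retained-intron transcript held 74.5% of the Etv1 TPM and the next, protein-coding transcript 13.2%. The layer 5 median exceeded that of layer 2/3 by 2.60 ± 0.97 on the log2 scale, that of layer 4 by 3.34 ± 0.12 and that of layer 6 by 3.29 ± 2.20, each more than 1 SD. The difference from layer 6 was 1.73 in replicate 1 and 4.84 in replicate 2. Restricting the lists to members at mean TPM of at least 1 lowered the difference from layer 4 to 2.20 ± 0.27. Without a reference tissue, differences between lists of different genes do not measure enrichment of layer 5 cells.

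Genes of other layers and of layer 5 subtypes were also detected. Layer 2/3 genes had medians of 4.59 and 3.23 TPM, with Lamp5 at 218 ± 146 TPM (SD, n = 2), Calb1 at 22.3 ± 9.77, Cux1 at 8.40 ± 5.68 and Cux2 at 2.75 ± 2.60. Layer 4 genes had medians of 1.02 and 3.42 TPM, with Plcxd2 at 13.6 ± 8.43, Rorb at 12.3 ± 9.55 and Kcnh5 at 2.88 ± 1.97. Layer 6 genes had medians of 5.33 and 0.44 TPM, with Rprm at 33.7 ± 13.1, Oprk1 at 41.2 and 0 TPM and Tle4 at 9.75 ± 7.28. Within layer 5, genes of extratelencephalic neurons, which project below the cortex, had medians of 6.13 and 7.39 TPM, with Ldb2 at 53.6 ± 12.6, Crym at 45.0 ± 6.61 and Parm1 at 32.6 ± 7.54. Genes of intratelencephalic neurons, which project within the forebrain, had medians of 5.48 and 20.0 TPM, with Dkkl1 at 67.8 ± 25.3 and Deptor at 21.7 ± 20.9. The extratelencephalic minus intratelencephalic difference of -0.48 ± 0.70 lay within the spread. Near-projecting genes were lower than extratelencephalic genes by 1.92 ± 0.11, with medians of 0.83 and 1.09 TPM and with Lypd1 at 9.88 ± 9.58, Tshz2 at 3.15 ± 2.32 and Vwc2l at 1.45 ± 0.42. The layer 5 list shares Fezf2, Bcl11b, Crym, Ldb2 and Parm1 with the extratelencephalic list and Etv1 and Deptor with the intratelencephalic list, so these lists are not independent.

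Genes of glutamate and GABA-A receptors and of ion channels were detected in each pool. The 15 ionotropic glutamate receptor genes had medians of 14.5 and 13.5 TPM, with 12 detected in each library, the AMPA receptor subunits Gria2 at 250.5 ± 6.77 TPM (SD, n = 2) and Gria3 at 95.2 ± 14.2 and the NMDA receptor subunit Grin2b at 93.2 ± 24.2. The 7 metabotropic glutamate receptor genes had medians of 10.4 and 13.3 TPM, with Grm5 at 43.7 ± 13.3, Grm3 at 22.2 ± 5.90 and Grm8 at 14.7 ± 1.94. All 12 GABA-A receptor genes were detected in each library, with medians of 40.9 and 40.1 TPM, with Gabra5 at 46.9 ± 1.75. All 8 sodium channel genes were detected, with medians of 49.2 and 46.0 TPM, with Scn2b at 193 ± 50.3 and Scn1a at 89.5 ± 8.94. Potassium and HCN channel genes had medians of 6.60 and 8.13 TPM, with 20 of 22 detected in each library and Kcnc1 at 48.0 ± 22.8 and Kcnma1 at 45.7 ± 0.98. Calcium channel genes had medians of 9.62 and 6.47 TPM, with Cacnb4 at 73.1 ± 8.34, Cacna2d1 at 25.4 ± 2.89 and Cacnb3 at 23.6 ± 0.37. Among 16 neuromodulator receptor genes, 10 were detected in each library, with medians of 3.65 and 3.52 TPM, and the highest were the muscarinic receptor Chrm1 at 14.9 ± 3.60 and the serotonin receptors Htr2c at 12.5 ± 0.50 and Htr1f at 11.02 ± 3.08.

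Genes of vesicle release and of basic metabolism were among the highest. The 17 synaptic vesicle genes had medians of 78.7 and 107 TPM, with the calcium sensor Syt1 at 511 ± 23.5 TPM (SD, n = 2) and the GTPase Rab3a at 358 ± 151. Nuclear genes of oxidative phosphorylation had medians of 729 and 762 TPM over 83 members, with Cox6c at 3087 ± 283 and Ndufa4 at 2882 ± 297 after Cox8a. The 80 cytosolic ribosomal protein genes had medians of 297 and 263 TPM, with Rpl41 at 1517 ± 247, Rpl38 at 823 ± 157 and Rps14 at 757 ± 67.0. Housekeeping genes had medians of 496 and 529 TPM, with Actb at 2018 ± 8.24 and Gapdh at 1713 ± 252. Immediate early genes, which neuronal activity induces, had medians of 5.37 and 5.41 TPM, with Homer1 at 79.0 ± 3.27, Egr1 at 38.1 ± 2.14 and Dusp1 at 10.1 ± 0.44. Heat shock genes had medians of 16.7 and 21.2 TPM, with Hsp90aa1 at 2037 ± 91.7, Hsph1 at 83.9 ± 10.2 and Dnajb1 at 34.3 ± 8.45.

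The 13 mitochondrially encoded protein genes had the highest medians of any list, at 4755 and 3759 TPM. The ATP synthase genes mt-Atp8 and mt-Atp6, which overlap on the mitochondrial chromosome (positions 7766 to 7969 and 7927 to 8607), stood at 13011 ± 2707 and 10484 ± 1265 TPM (SD, n = 2), and the cytochrome gene mt-Cytb at 7300 ± 431. Reads of mt-Atp6 were uncertain, since the posterior SD of its count in replicate 2 was 0.25 of the count. Of 8 annotated pseudogenes at mean TPM of at least 1000, 6 lie on chromosome 1, and 97.2% to 100% of the 31-mers of their transcripts also occur in transcripts of the mitochondrial chromosome. These 6, among them Gm28437 at 17823 TPM and Gm29216 at 13856 TPM in the mean, held 2.76% and 2.37% of gene counts. Together with the mitochondrial genes they held 8.66% and 7.67%, so the mitochondrial share given above is too low if these reads are mitochondrial. The other 2, Gm10123 on chromosome 9 and Gm10221 on chromosome 5, shared 0% of their 31-mers. Gm37376 (chromosome 19, 5801941 to 5802393, plus strand) stood at 31221 and 27071 TPM inside the interval of the noncoding RNA Malat1 (5795690 to 5802672, minus strand), which stood at 39191 and 34798 TPM. Their counts in replicate 1 were 221053 and 387922, with a posterior SD of 134 for each gene, and their SDs in replicate 2 were likewise equal at 137. SDs this equal would arise if the 2 genes divided the same reads, so the level of Gm37376 cannot be read apart from that of Malat1. Strand use in the counting was not given in the sources used here, so how many reads these overlapping genes share is left open. Malat1, Gm37376 and the pseudogenes were named after their values were seen.

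Across 22057 genes the libraries were related with Pearson r = 0.967 and Spearman rho = 0.908 on log2(TPM + 1), although genes are not independent replicates. They were not duplicates of 1 library. An exact conditional binomial test, which compares these 2 libraries and not conditions, gave p under 0.05 for 12327 of 17796 genes, and 11917 remained after Benjamini-Hochberg adjustment. This test allows for counting error only, so it does not separate biological from technical differences. The common biological coefficient of variation was 0.526 over 17816 genes. It fell with abundance, from 1.15 in the lowest of 4 abundance groups of genes to 0.211 in the highest, and was 0.360 over 70 spike-ins.

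Of 9189 genes at mean CPM of at least 10, 4.47% differed at least 2-fold between the pools, against 10.4% of 14332 genes at mean CPM of at least 1 and 7.21% with spike-in totals. At the higher minimum 241 were higher in replicate 1 and 170 in replicate 2, with 52 and 15 at least 4-fold. Of these 2-fold differences 58.6% were higher in replicate 1. Scaling to spike-in totals moved the median log2 ratio of genes at mean CPM of at least 10 from -0.02 to 0.33. It gave 606 and 59 genes, 91.1% higher in replicate 1. With 1 library on each side the differences have no replicate check, and reads without molecular identifiers mean that intervals and floors cover counting error only.

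The 10 highest ratios toward replicate 1 included those of Vip, Oprk1, Nr4a2 and Penk. The vasoactive intestinal peptide gene Vip (chromosome 10, 5639218 to 5647617) had 4365 reads in replicate 1 and 1 read in replicate 2, a ratio of CPM of 4895 with a 95% exact counting interval of 878 to 193380. The kappa opioid receptor gene Oprk1 (chromosome 1, 5588466 to 5606131) had 3206 reads and 0 reads, at least 1198-fold higher in replicate 1 against a floor of 3 reads in the other library. Nr4a2, a nuclear receptor, stood at 133 and 0.89 TPM, 258-fold higher by CPM, and the enkephalin precursor Penk at 101 and 1.64 TPM, 74.4-fold higher. Gnb4 was 31.2-fold higher, Rgs12 30.3-fold, Sema5a 28.3-fold, Rxfp1 18.8-fold and Sulf1 216-fold. Angpt1 had 477 reads and 1 read, a ratio of 535 with an interval of 95.5 to 21171.

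Genes higher in replicate 2 were led by the hemoglobin genes. Hbb-bs was 148-fold higher by CPM in replicate 2, at 1.03 and 133 TPM, Hba-a2 57.5-fold higher and Hba-a1 48.1-fold higher. Reads of these paralogs are shared, with a posterior SD of 0.31 of the count for Hba-a1 in replicate 1. Tmem215 was 8.01-fold higher, Grm2 7.39-fold, Vtn 7.30-fold, Il1rapl2 6.96-fold, Scube1 6.49-fold and Etv1 5.48-fold.

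**Figure D2:**
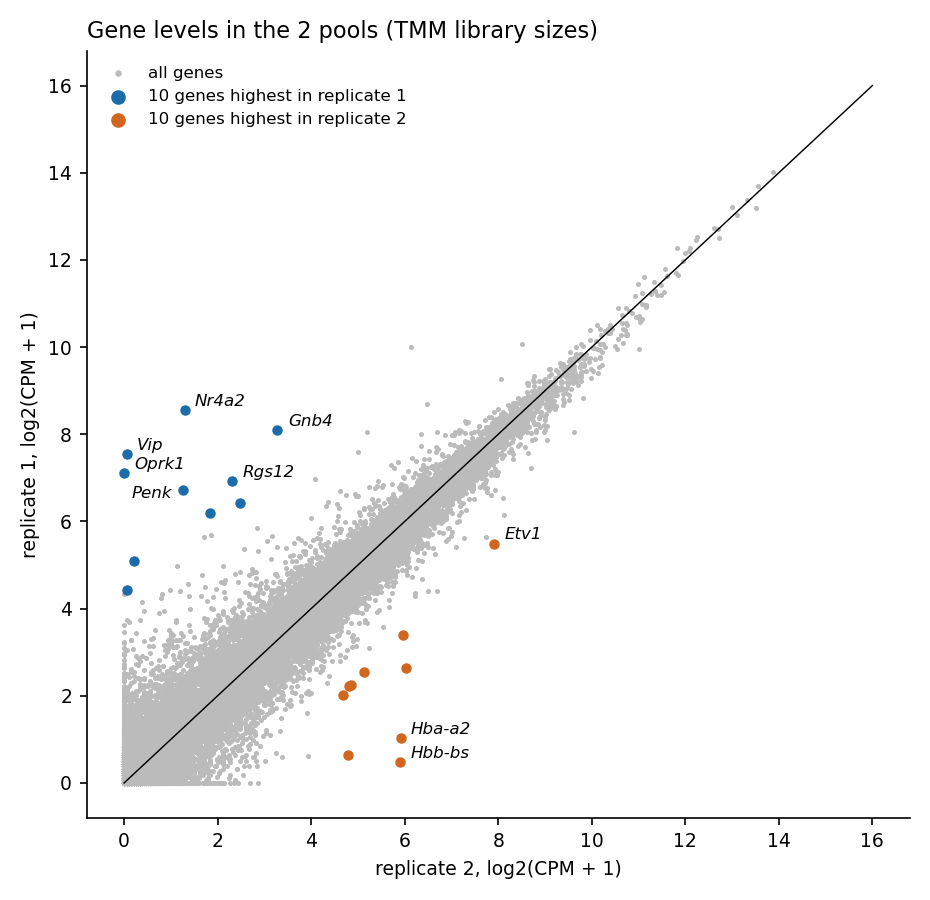
Each point is 1 gene, drawn at log2(CPM + 1) in replicate 2 (x) and replicate 1 (y) with TMM library sizes; the line marks equal values. The 10 genes with the highest and the 10 with the lowest ratio among genes at mean CPM of at least 10 are coloured, and some are named, such as Vip with 4365 reads and 1 read.

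Layer 6 genes were higher in replicate 1, and most intratelencephalic layer 5 genes were higher in replicate 2. All 5 layer 6 genes at mean CPM of at least 10 were higher in replicate 1, with a median log2 ratio of 2.92, above all 10000 random lists matched on mean expression. Foxp2, a layer 6 transcription factor, stood at 7.73 and 0.44 TPM, Tle4 at 14.9 and 4.60 and Rprm at 42.9 and 24.4. The median member was Syt6, named for that after its values were seen, so the median did not depend on the value given to Oprk1. All 5 intratelencephalic genes at that minimum were higher in replicate 2, with a median of -2.09, below all random lists, and -0.76 over 7 members at mean CPM of at least 1, of which 2 were higher in replicate 1. Etv1 stood at 15.5 and 93.6 TPM and Deptor at 6.89 and 36.5. The 10 layer 5 genes had a median of -0.78, below all random lists, with Fezf2 at 20.0 and 44.4 TPM and Pcp4 at 2134 and 4468, but Bcl11b at 12.2 and 10.2. This median was -0.49 over 11 members at mean CPM of at least 1 and -0.42 with spike-in totals.

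Interneuron and microglial genes were higher in replicate 1, and erythroid genes in replicate 2. Of 10 interneuron genes 8 were higher in replicate 1, with a median log2 ratio of 0.61, above all random lists, and 0.95 with spike-in totals. All 7 microglial genes were higher in replicate 1, with a median of 1.20, above all random lists, such as C1qb at 39.4 and 13.9 TPM. The 3 erythroid genes had a median of -4.89, below all random lists. The erythroid gene Alas2, below the CPM minimum and named after its values were seen, stood at 0.68 and 1.14 CPM, 1.66-fold higher in replicate 2, although its TPM was 1.23 and 1.00.

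**Figure D3:**
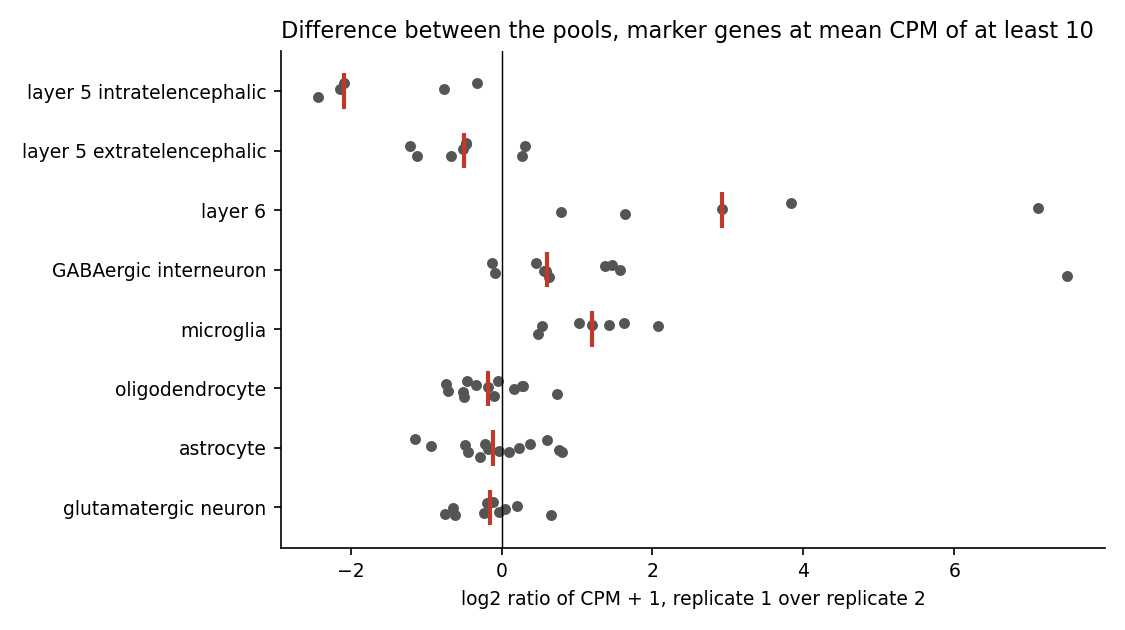
Log2 ratio of CPM + 1 between replicate 1 and replicate 2 for genes of 8 marker lists at mean CPM of at least 10; each point is 1 gene and the red bar is the list median. The layer 6 median lies at 2.92 and the intratelencephalic median at -2.09, whereas the glutamatergic, astrocyte and oligodendrocyte medians lie at -0.15, -0.11 and -0.18. These 3 turn positive with spike-in totals, a scaling that raises the ratios of genes in general.

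Other marker lists also lay apart from random lists. Both oligodendrocyte precursor genes were higher in replicate 1 with a median of 1.55 (percentile 99.5), and both layer 4 genes were higher in replicate 2 with a median of -1.52 (percentile 0). The 2 mural genes had a median of -1.53 (percentile 0.13), against -0.52 over 8 genes at mean CPM of at least 1, where the mean was -0.03 and 3 genes were higher in replicate 1. The 8 extratelencephalic genes had -0.50 (percentile 0.17), or -0.12 with spike-in totals. The layer 2/3 median over 5 genes was 1.30 (percentile 99.99), with Cux1 at 12.4 and 4.38 TPM, but Lamp5, at 115 and 321 TPM, was the member left at mean CPM of at least 100 and gave -1.47. The near-projecting list held only Lypd1 above the minimum, at 1.89 (percentile 98.5), and its median was -0.51 over 3 genes at mean CPM of at least 1. The 3 fibroblast genes at that lower minimum had a median of 1.85 (percentile 99.6). No member of the ependymal and choroid plexus list or of the X-inactivation list entered these ratios.

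Pan-neuronal and vesicle genes were slightly higher in replicate 2 relative to other genes. The pan-neuronal median was -0.34 (percentile 0.24), with 13 of 15 genes higher in replicate 2, and it turned to 0.02 with spike-in totals. For synaptic vesicle genes the median was -0.40 (percentile 0.01), or -0.04 with spike-in totals, with Rab3a at 251 and 464 TPM. The pan-neuronal and vesicle lists share members, among them Snap25 and Syt1, so these results are not independent. Sodium channel genes had a median of -0.37 (percentile 0.64), or -0.02 with spike-in totals, but a mean of -0.01, with 5 of 8 genes higher in replicate 2. Ribosomal protein genes were higher in replicate 1 in 67 of 77 cases, with a median of 0.18 (percentile 100), as were mitochondrially encoded genes at 0.18 (percentile 99.8), ionotropic glutamate receptor genes at 0.26 (percentile 99.3) and nuclear genes of oxidative phosphorylation at 0.03 (percentile 98.8). With spike-in totals these medians were 0.54, 0.54, 0.62 and 0.39, and the ionotropic median was 0.06 at mean CPM of at least 100. Medians within the central 95% of random lists were -0.15 for glutamatergic, -0.11 for astrocyte, -0.18 for oligodendrocyte and -0.16 for endothelial genes, -0.29 for metabotropic glutamate receptor, -0.12 for potassium and HCN channel and -0.03 for calcium channel genes, and -0.25 for heat shock and -0.16 for housekeeping genes, and all 9 turned positive with spike-in totals. Spike-in scaling raised the median log2 ratio of genes at mean CPM of at least 10 from -0.02 to 0.33, so these turns are not particular to the 9 lists. The means of the potassium and HCN channel and calcium channel lists were 0.03 and 0.06, opposite in sign to their medians. The remaining medians in that range were 0.01 for GABA-A receptor, 0.21 for neuromodulator receptor, 0.12 for immediate early and 0.09 for Y-linked genes. At mean CPM of at least 1 the metabotropic median was -0.44 (percentile 1.10), outside that range, and the neuromodulator median was -0.13. At mean CPM of at least 100 the metabotropic, potassium and HCN channel and GABA-A receptor medians were 0.59, 0.18 and -0.07, each opposite in sign.

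Transcript values were used for replicate 1 only, so they have no replicate. Among 6895 genes at TPM of at least 10, 3149 (45.7%) had a transcript holding at least 90% of the gene's TPM. Over the 5165 genes with at least 2 annotated transcripts this share was 27.5%. Camk2a was carried by Camk2a-203 at 97.0%, and the leading transcripts of Gad2, Pvalb and Bcl11b held 96.6%, 98.6% and 98.4%. Mbp was more mixed, with Mbp-211 at 74.6%. The leading transcripts of Tle4 and Ddx3y held 74.2% and 72.7%, while Sst, Vip, Nefh, Fezf2, Thy1 and Slc17a7 have 1 transcript each. In 607 of 5031 coding genes with several transcripts (12.1%) the leading transcript was annotated as noncoding, such as Gad1-206 at 85.0% of Gad1, the retained-intron transcript Etv1-212 at 74.5% of Etv1 and Eif2s3y-206 at 55.5% of Eif2s3y. Among coding genes at TPM of at least 100, the lowest leading shares were those of Atrx (21.9%), Ptprd (23.1%), Arpp21 (23.4%), Ppig (23.4%) and Cryzl1 (24.2%).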

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

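Features outside the gene comparisons held few reads. The 26248 entries with numeric identifiers held 8 reads in replicate 1 and 15.1 in replicate 2, above the 3 reads that a count of 0 allows, and they were singled out because no comparison used them. Gene identifiers without a match in the annotation held 0.194% of gene counts in replicate 1 and 0.179% in replicate 2 and were singled out for the same reason. No explanation of these reads was tested.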

How the results depend on the processing

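The 4 abundance groups and spike-ins as subsets, the list ratios at mean CPM of at least 1, the genes with at least 2 transcripts and the interneuron list without its 4 highest genes were chosen after the data were seen; the other alternatives were fixed before. Limits for a shift were 1 SD for differences of list medians, the SD of random lists for list ratios, 1.5 times for counts and coefficients, and the 95% interval for correlations and shares. For the main results 53 alternative values passed these limits, none of the 53 with a change of sign. Among the other results 88 passed the limits and 3 more changed sign, those of the pan-neuronal, near-projecting and layer 2/3 ratios given below. A change of sign was counted only for differences beyond 1 SD and for ratios outside the central 95% of random lists. With the mean over members, the glutamatergic difference was 1.84 from interneuron, 1.43 from astrocyte, 1.21 from oligodendrocyte and 3.29 from endothelial genes, and the layer 5 to layer 4 difference was 3.53. With members at mean TPM of at least 1, the interneuron, endothelial, layer 4 and near-projecting differences were 2.54, 3.07, 2.20 and 1.74. A pseudocount of 0.1 gave 2.14 for astrocyte, 4.42 for endothelial, 3.93 for layer 4 and 2.72 for near-projecting genes. Rescaling to nuclear coding genes gave 3.52 for layer 4 and 2.13 for near-projecting genes, and FPKM gave 1.79 for the latter. Without Sst, Npy, Pvalb and Vip the interneuron difference was 3.56. No ependymal gene was left at mean TPM of at least 1. Genes detected in the mean numbered 6877 at TPM of at least 10, 18596 at TPM of at least 0.1, 19782 at a count of at least 1 and 17342 at a count of at least 5, fewer or more by construction. Pearson r was 0.918 with a pseudocount of 0.1, 0.969 with FPKM, 0.973 over nuclear coding genes and 0.963 over genes with counts summing to at least 100. Spearman rho was 0.959 over nuclear coding genes, 0.942 at counts of at least 10 and 0.952 at counts of at least 100. The coefficient of variation was 0.336 at counts of at least 100, and 1.15, 0.282 and 0.211 in abundance groups 1, 3 and 4. Genes at least 2-fold higher in replicate 1 and in replicate 2 numbered 606 and 59 with spike-in totals, 926 and 561 at mean CPM of at least 1, and 22 and 18 at mean CPM of at least 100. With spike-in totals the median list ratios were 0.95 for interneuron, 1.53 for microglial, -0.42 for layer 5, -1.74 for intratelencephalic and 3.20 for layer 6 genes, and the pan-neuronal median turned from -0.34 to 0.018. At mean CPM of at least 1 they were -4.52 for erythroid, -0.49 for layer 5, -0.76 for intratelencephalic and 2.66 for layer 6 genes, and the near-projecting median turned from 1.89 to -0.51. At mean CPM of at least 100 they were 0.98 for interneuron and -1.06 for layer 5 genes, and the layer 2/3 median turned from 1.30 to -1.47. A pseudocount of 0.1 CPM gave -5.71 for erythroid and 3.46 for layer 6 genes. The share of genes with a dominant transcript was 53.7% and 52.6% at gene TPM of at least 1 and 100, 54.4% with a limit of 80%, 43.9% over coding genes and 27.5% over genes with at least 2 transcripts. Apart from changes in which genes were counted, the cause of these shifts was not tested. No paired analysis was possible because there was 1 group. Leaving out a replicate leaves the value of the other, without a test. With 2 libraries each value lies within 1 SD of their mean, so for differences of list medians this alternative could not pass its limit. The erythroid difference then ranged from -0.11 to 4.63, the microglial from 1.70 to 4.17, the layer 6 from 1.73 to 4.84 and the extratelencephalic minus intratelencephalic difference from -0.97 to 0.02, so the first and the last changed sign with 1 library left. Thinning replicate 2 to the depth of replicate 1 gave 13672 detected genes against 13690.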

Other observations

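The tests of unscaled layer 6 reads and of the lists with and without layer 5 genes were chosen after their result was seen, and the patterns themselves were noticed in these data.

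Interneuron transcripts were found in each pool of cells captured as pyramidal neurons. Reads shared between similar genes were argued against, since the median posterior SD over the count was 0 over 15 interneuron genes in each library. RNA from interneurons in the captured material and expression of these genes by the captured pyramidal neurons were not tested, and both stay open.

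Layer 6 genes were higher in replicate 1, with a median log2 ratio of 2.92. A difference in library size was argued against, since all 5 layer 6 genes at mean CPM of at least 10 had more unscaled reads in replicate 1, the library with fewer reads. The scaled ratios, the smallest of them 1.76-fold for Rprm, already implied this, so it adds no separate evidence. RNA from layer 6 cells stays open, since the list that raised it cannot test it, and so does chance in which cells were sampled, which spike-ins do not carry. A narrower hypothesis is RNA from claustrum-like or layer 6 Car3-type cells, raised by Nr4a2, Gnb4, Oprk1 and Rxfp1 among the highest ratios. Of 6 markers then listed for it, Smim32 was not matched. The other 5 were Ntng2, Lxn, Car3, Synpr at 489 and 33.4 TPM and Gng2 at 255 and 61.9 TPM. At mean CPM of at least 1 these 5 had a median of 2.57, above 100% of matched random lists. Ntng2 and Car3, at mean CPM of 1.57 and 4.72, lay below the minimum of 10 used for layer 6 genes, and Ntng2 had the smallest log2 ratio, 0.78. Interneurons also express Synpr, and loss of RNA before spike-ins were added was not tested. The hypothesis came from ratios of the same libraries, and the random lists were matched on mean expression only. The marker result therefore cannot tell this source from other cells that express these markers.

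Genes of the cell type and layer lists, those of layer 5 included, differed more between the pools than other genes of like abundance. Over 86 genes of the non-neuronal, interneuron and layer lists the median absolute log2 ratio was 0.72, against 0.27 for matched random lists, and 100% of those lists had a smaller value. It was 0.71 over 69 genes outside the layer 5 lists and 0.76 over the 17 layer 5 genes, so the pattern is not particular to markers of other cells. Yet the median ratios of the astrocyte (-0.11, percentile 26.7), oligodendrocyte (-0.18, percentile 12.1) and endothelial lists (-0.16, percentile 25.9) lay within the range of random lists. A difference in the share of some cell types may account for the pattern, as a hypothesis found and tested on the same libraries, and with 1 group in the labels no biological explanation across groups was tested.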
